A study of Homo sapiens with 4 samples.

How the data were processed

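Total RNA from BJ human skin fibroblasts was measured in 4 libraries, 2 from DMSO-treated and 2 from Dox-treated cells, grouped by their titles. The series design places the 24 hours of treatment before the 10 days, whereas the wording of the samples' treatment protocol can be read as the reverse order, and the former is used here. Cutadapt, STAR, Picard, RSEM and the build hg38 are named in the submitters' processing notes, and their versions and the annotation release are not given in the sources used here. Each deposited table lists 58870 genes. The deposited expected counts are named so per the file headers, and are estimated reads per gene that need not be whole. The deposited TPM values are named so per the file headers, a unit scaled by transcript length and to one total per library. The deposited FPKM values are likewise named per the file headers and were not used here.

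Expected counts were rounded to whole numbers. The 555 rows of Y-linked genes and XIST were left out throughout. Of the gene identifiers, 99.5% matched GENCODE 29 (GRCh38) by Ensembl identifier, and coordinates are those of GENCODE 29, 1-based. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, scaled by TMM and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), with group as the only term. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and CPM values were TMM-scaled. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The 20 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 20 lists. No list passed with an estimated correlation. With an estimate, camera tests on the residual degrees of freedom of only 4 libraries, so it has little power here. Estimates ran from -0.0197 (mitosis) to 0.983 (mitochondrially encoded mRNAs). Where the estimate lay below 0.01, as for mitosis, correlation among members did not remove the call. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 were used.

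The design, the gene lists, the cell type markers, the rule for named genes and the first set of alternatives were chosen before the data were examined. Named genes were 16 centromere, cell cycle and senescence genes, the 5 largest rises and 5 largest falls among genes past the threshold with a mean of at least 1 CPM and groups that did not overlap, and, for each list with at least 5 measured members, the 2 with the smallest adjusted p in its commoner direction. The rule left open a list in which as many rose as fell; in the unfolded protein response list, both directions entered. Apart from the fixed cell type markers, all other genes were named after their values were seen. The values of some genes that the rule or the lists name are not reported here. Intervals for ratios of counts are exact conditional binomial intervals, shares carry Wilson intervals, and both cover counting error only.

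The libraries held 16074 and 16332 (control) and 16711 and 16833 (Dox) genes with at least 10 counts. Over genes with at least 20 summed counts, the chi-square per degree of freedom between replicates was 2.4 for the control pair and 60.6 for the Dox pair, so both pairs differed by more than sampling noise and each library was counted once. The first principal component (76.8% of the variance) separated the groups, and the second (14.7%) separated the Dox libraries from each other. The log2 ratio of the Dox libraries followed transcript GC content (Spearman rho over 16682 genes = -0.59, genes not being independent replicates), against -0.0294 for the control pair and -0.0323 for Dox over control. The small RNAs RN7SL1 and RN7SL2 took 17.6% (17.56 to 17.58%) and 17.4% (17.35 to 17.38%) of control counts, and 14.7% (14.71 to 14.73%) and 12.6% (12.61 to 12.63%) of Dox counts, with Wilson 95% intervals. On counts simulated for Dox against control (16396 genes tested), 200 genes were changed by 1.5-, 2- or 4-fold and a further list of 40 was raised 1.5-fold. Of the changed genes that were tested, the gene test recovered 50.0% of 1.5-fold, 80.9% of 2-fold and 97.1% of 4-fold changes, with 5 false calls. The simulated counts had the same dispersion trend in both groups, no gene-wise spread and no GC trend, unlike the real libraries. These figures are therefore no estimate of recovery or false calls in the real data. Alternatives were other scalings, filters and tests, TPM on a log scale with pseudocounts of 1 and 0.1, a fold threshold of 1.5, the replicate number as a block, the removal of mitochondrially encoded genes and leaving out each library. Offsets for GC trends, protein-coding genes alone and sample quality weights were added after seeing the data.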

Results

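RNA from BJ cells, a line of human skin fibroblasts, was sequenced in 4 libraries. In 2 of them the cells had received the solvent DMSO (control), and in the other 2 they had received 250 nM of a compound that the labels abbreviate as Dox. The exposure lasted 24 hours and was followed by 10 days in which the cells were left to senesce, as the series design describes it. The sample titles call the control libraries young and the Dox libraries aged. Expected counts summed to 42710455 and 47760726 in the control libraries, and to 42844784 and 43392296 in the Dox libraries. The series title concerns centromere inactivation during ageing, and the comparison of Dox with control asks which transcripts differ between Dox-treated and DMSO-treated fibroblasts.

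In the Dox libraries 36 of 44 measured mitosis genes were lower, and 34 of 42 senescence-associated secretory genes, 22 of 34 p53 targets and 21 of 30 interferon-stimulated genes were higher, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. KIF20A, a mitotic kinesin, fell from 10.7 ± 0.224 CPM (SD, n = 2) to 2.15 ± 0.0228 CPM (SD, n = 2). MMP3, a secreted metalloproteinase, rose from 6.11 ± 0.213 CPM (SD, n = 2) to 95.1 ± 0.585 CPM (SD, n = 2). CENPA, the centromeric histone H3 variant, fell from 1.24 ± 0.298 CPM (SD, n = 2) to 0.443 ± 0.00244 CPM (SD, n = 2). CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 467 ± 0.401 CPM (SD, n = 2) to 920.0 ± 101 CPM (SD, n = 2). By the same test, 2757 of 16714 tested genes were higher in Dox and 2306 were lower at an adjusted p under 0.05. Of these, 1042 were at least 2-fold higher and 559 at least 2-fold lower in the fitted values. Both Dox libraries lay on the same side of both control libraries for 69.1% of all tested genes, where chance gives 33.3%. Leaving out control replicate 1 gave 1533 higher and 1106 lower genes, leaving out control replicate 2 1438 and 1075, leaving out Dox replicate 1 4499 and 4574, and leaving out Dox replicate 2 4613 and 5041. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Without control replicate 1 or control replicate 2, 14 and 14 of the p53 targets were higher. With limma on log2(TPM + 1), limma on log2(TPM + 0.1) and edgeR's glmTreat at a 1.5-fold threshold in turn, 9, 8 and 27 mitosis genes were lower, and 26, 28 and 29 secretory genes, 4, 4 and 9 p53 targets and 6, 9 and 13 interferon-stimulated genes were higher.

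**Figure D1:**
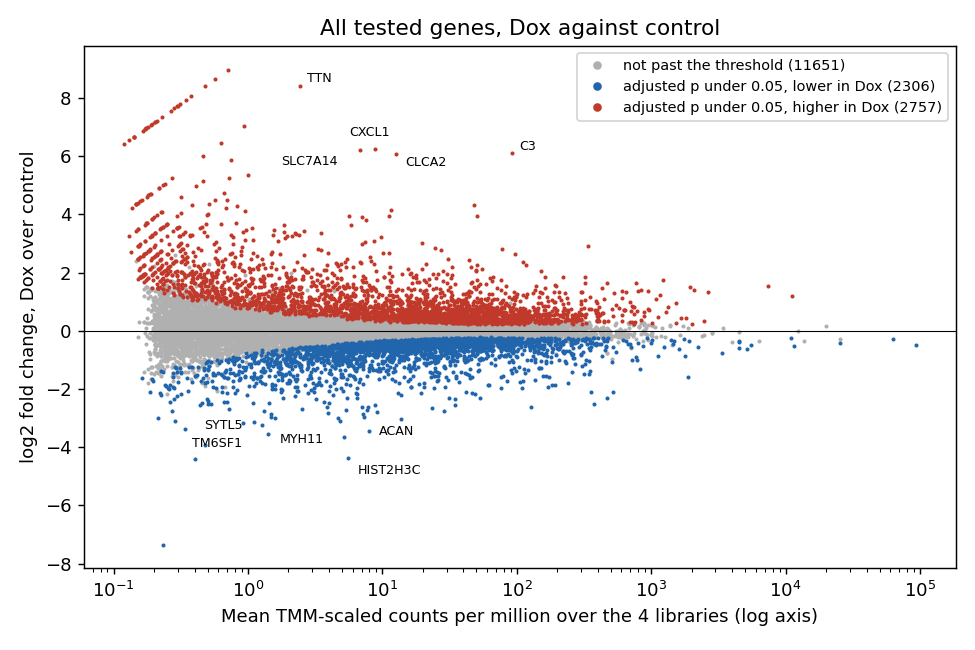
Each point is a tested gene, placed by its mean TMM-scaled CPM over the 4 libraries (x, log axis) and its log2 fold change of Dox over control (y). Red points (2757) were higher and blue points (2306) lower at an adjusted p under 0.05, grey points did not pass, and the 5 largest rises and 5 largest falls among genes with a mean of at least 1 CPM carry their symbols; for the 27 red points with 0 counts in both controls the height depends on the prior count and is no estimate of size.

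The largest rises among genes with a mean of at least 1 CPM were those of TTN, CXCL1, SLC7A14, C3 and CLCA2. TTN, which encodes the sarcomere protein titin (chromosome 2, 178525989 to 178830802 in GRCh38), had 1 and 0 counts in the control libraries and 223 and 203 in the Dox libraries, a ratio of 428 with an exact 95% counting interval of 76.5 to 16960. CXCL1, a neutrophil-attracting chemokine (chromosome 4, 73869393 to 73871242), had 10 and 10 counts in the control and 796 and 728 in the Dox libraries (edgeR log2 fold change 6.24, SE 0.19, adjusted p = 4.94e-05). C3, the central complement component (chromosome 19, 6677704 to 6730562), rose from 2.63 ± 0.455 CPM to 180.5 ± 13.5 CPM (SD, n = 2 each, edgeR log2 fold change 6.11, SE 0.14, adjusted p = 3.96e-05). SLC7A14, a member of the cationic amino acid transporter family, rose by 6.21 and CLCA2, a membrane protein, by 6.09 on the log2 scale, each with an edgeR adjusted p of 4.43e-05. The largest falls were those of HIST2H3C, MYH11, TM6SF1, ACAN and SYTL5. MYH11, the smooth muscle myosin heavy chain (chromosome 16, 15703172 to 15857033), fell by 3.66 (SE 0.19, edgeR adjusted p = 0.000123), and ACAN, the cartilage proteoglycan aggrecan, fell by 3.45 (SE 0.22, edgeR adjusted p = 0.000232). TM6SF1 fell by 3.56 and SYTL5 fell by 3.25 on the same scale. The value of HIST2H3C is uncertain because the near-identical copy HIST2H3A shares its reads, with 592 and 333 control counts against 45 and 0 Dox counts assigned to HIST2H3C. The counts of HIST2H3A, HIST2H3C and HIST2H3D summed to 635 and 743 in the control and 117 and 139 in the Dox libraries. DESeq2's Wald test gave HIST2H3C an adjusted p of 0.286, within a range of 3.62e-151 to 0.286 over its alternatives.

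Among genes that place and hold the centromeric histone, CENPA, its chaperone HJURP and the loading factor OIP5 fell, while CENPB, CENPC and MIS18A did not pass the test. CENPA (chromosome 2, 26764289 to 26801067) had 43 and 68 counts in the control and 19 and 20 in the Dox libraries (log2 fold change -1.49, SE 0.29, adjusted p = 0.0116 by edgeR). HJURP (chromosome 2, 233833416 to 233854566) fell from 5.89 ± 0.722 CPM to 2.32 ± 0.0325 CPM (SD, n = 2 each, edgeR log2 fold change -1.34, SE 0.16, adjusted p = 0.00198). OIP5, which directs CENPA loading, had 33 and 29 control and 8 and 12 Dox counts (edgeR log2 fold change -1.62, SE 0.34, adjusted p = 0.0161). The log2 fold changes were -0.24 (SE 0.16) for the alpha-satellite binding protein CENPB, -0.06 (SE 0.10) for the inner kinetochore protein CENPC and -0.32 (SE 0.15) for MIS18A. Of the 26 measured genes of CENP-A loading and the inner kinetochore, 9 fell, 1 rose and 16 did not pass, with the same counts when adjusted over the list alone. RBBP7, a histone-binding protein, fell by 0.61 (SE 0.07), and the gene that rose was CENPT (0.43, SE 0.11), named after its value was seen. The list's median was -0.28, and camera gave adjusted p = 0.00385, or adjusted p = 0.174 with an estimated correlation. CENPA did not pass without control replicate 2 (edgeR adjusted p = 0.0684, range 6.31e-05 to 0.206 over all alternatives), nor OIP5 without control replicate 1 (edgeR adjusted p = 0.0972, range 0.000856 to 0.112). CENPB was at 28.3 CPM in Dox replicate 1 and 40.8 CPM in Dox replicate 2, against 41.5 and 40.1 CPM in the control libraries. Its lower Dox mean therefore rested on Dox replicate 1. Leaving out control replicate 1, control replicate 2, Dox replicate 1 and Dox replicate 2 in turn, 5, 5, 15 and 12 genes of this list fell and 0, 0, 1 and 2 rose, and with GC-trend offsets 15 fell. Under log2(TPM + 1), log2(TPM + 0.1) and a 1.5-fold threshold in turn, 1, 1 and 2 fell and 0, 0 and 0 rose, and the medians on the TPM scales were -0.08 and -0.14.

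**Figure D2:**
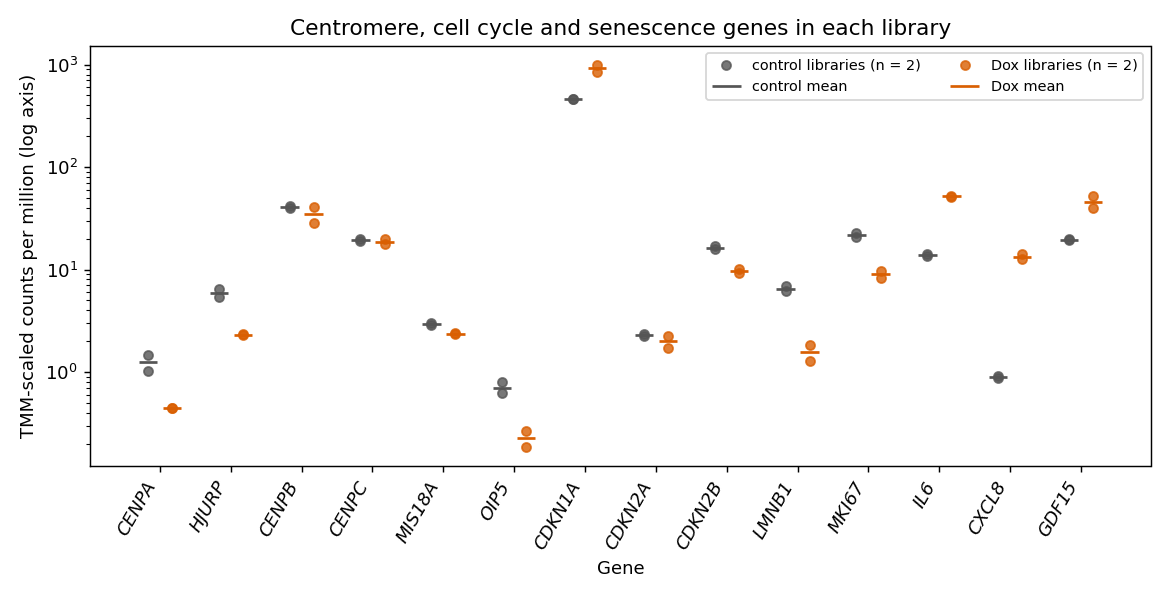
Points are TMM-scaled CPM (log axis) of centromere, cell cycle and senescence genes in each of the 2 control (grey) and 2 Dox (orange) libraries, and lines are group means. The CENPA means were 1.24 CPM in control and 0.443 in Dox, and the CXCL8 means 0.893 and 13.3.

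Of 44 measured mitosis genes, 36 fell, 0 rose and 8 did not pass (median log2 fold change -1.26), while 1 rose and 37 fell when adjusted over the list alone (the riser being SMC2, 0.26, named after its value was seen). KIF20A fell by 2.32 (SE 0.13), TOP2A, the topoisomerase of dividing cells, fell by 1.40 (SE 0.08) and the proliferation marker MKI67 fell by 1.27 (SE 0.12, edgeR adjusted p = 0.000791). Camera gave the mitosis list adjusted p = 3.4e-24, or adjusted p = 0.0647 with an estimated correlation. In the outer kinetochore and spindle checkpoint list, 20 of 30 genes fell, 0 rose and 10 did not pass (median -0.97), and 0 rose and 21 fell when adjusted over the list alone. BIRC5, a chromosomal passenger protein, fell by 1.81 (SE 0.15) and the microtubule-binding NDC80 fell by 1.85 (SE 0.17), and camera gave the list adjusted p = 4.18e-10, or adjusted p = 0.0969 with an estimated correlation. DNA replication genes fell in 24 of 45 cases and 18 did not pass (median -0.56), while 3 rose and 30 fell when adjusted over the list alone. RRM2, a ribonucleotide reductase subunit, fell by 1.29 (SE 0.12) and the helicase subunit MCM7 fell by 0.68 (SE 0.09). The 3 replication genes that rose, named after their values were seen, were PCNA (0.40), TYMS (0.73) and PRIM2 (1.06), and camera gave the list adjusted p = 2.07e-05, or adjusted p = 0.0969 with an estimated correlation. Replication-dependent histone genes fell in 52 of 65 cases, 0 rose and 13 did not pass (median -1.29), and 0 rose and 58 fell when adjusted over the list alone. HIST1H3G fell by 2.71 (SE 0.15) and HIST1H4J fell by 1.42 (SE 0.07), where single-gene values are uncertain since many histone genes have near-identical copies. Camera gave the histone list adjusted p = 3.45e-27, or adjusted p = 0.0969 with an estimated correlation. Homologous recombination and Fanconi anaemia genes fell in 13 of 31 cases and 17 did not pass (median -0.45), while 1 rose and 16 fell when adjusted over the list alone. BARD1, the partner of BRCA1, fell by 1.30 (SE 0.12) and FANCI fell by 0.54 (SE 0.10), while FANCM (0.64), named after its value was seen, was the 1 member that rose. Camera gave this list adjusted p = 0.00158, or adjusted p = 0.212 with an estimated correlation. FANCI did not pass without control replicate 1 (edgeR adjusted p = 0.086) or control replicate 2 (0.0927), with a range of 1.01e-08 to 1. With control replicate 1, control replicate 2, Dox replicate 1 and Dox replicate 2 left out in turn, 7, 4, 21 and 18 recombination genes fell and 0, 0, 1 and 3 rose, 16, 15, 30 and 32 replication genes fell, and 0, 0, 2 and 2 mitosis, 0, 0, 0 and 1 outer kinetochore and 0, 1, 0 and 0 histone genes rose. Under log2(TPM + 1), log2(TPM + 0.1) and a 1.5-fold threshold in turn, 9, 8 and 27 mitosis, 9, 6 and 14 outer kinetochore, 0, 0 and 2 replication, 19, 19 and 34 histone and 1, 0 and 1 recombination genes fell, and 0, 0 and 1 replication and 0, 0 and 0 recombination genes rose. The medians on the TPM scales were -0.30 and -0.77 for mitosis, -0.19 and -0.69 for outer kinetochore, -0.08 and -0.28 for replication, -0.77 and -1.12 for histone and -0.07 and -0.20 for recombination genes. DESeq2's Wald test gave 6 falls among recombination genes and sample quality weights 8.

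Senescence-associated secretory genes rose in 34 of 42 measured cases, 6 fell and 2 did not pass (median log2 fold change 1.80), with the same counts when adjusted over the list alone. MMP3 rose by 3.96 (SE 0.08) and the collagenase MMP1 by 2.82 (SE 0.08). The chemokine CXCL8 rose by 3.90 (SE 0.15, edgeR adjusted p = 7.17e-05) and the cytokine IL6 by 1.90 (SE 0.08, edgeR adjusted p = 8.75e-05). CXCL12, a chemokine of stromal cells, fell by 2.34 and INHBA, an activin subunit, fell by 1.85, both named after their values were seen, and HGF (-0.47) and ANGPTL4 (0.25) did not pass. Camera gave the secretory list adjusted p = 9.86e-41, or adjusted p = 0.0647 with an estimated correlation. Of 34 p53 target genes, 22 rose, 1 fell and 11 did not pass (median 0.50), and 24 rose and 1 fell when adjusted over the list alone. CDKN1A (chromosome 6, 36676460 to 36687339) rose by 0.98 (SE 0.09, edgeR adjusted p = 0.000934), GDF15, a stress-induced secreted factor, by 1.23 (SE 0.13), the actin regulator CYFIP2 by 2.14 (SE 0.11) and the decoy death receptor TNFRSF10C by 2.35 (SE 0.15). SESN2, a stress-induced metabolic regulator named after its value was seen, was the 1 target that fell (-0.62), and camera gave the list adjusted p = 4.18e-10, or adjusted p = 0.0969 with an estimated correlation. CDKN2A, which encodes a kinase inhibitor tied to senescence, had a log2 fold change of -0.20 (SE 0.20) and did not pass the test. CDKN2B, its neighbour and relative, fell by 0.76 (SE 0.10, edgeR adjusted p = 0.00293). Interferon-stimulated genes rose in 21 of 30 cases, 0 fell and 9 did not pass (median 0.83), and 22 rose and 0 fell when adjusted over the list alone. IFI6 rose by 1.46 (SE 0.07) and the antiviral RNA sensor OAS3 by 2.07 (SE 0.12), and camera gave the list adjusted p = 4.64e-12, or adjusted p = 0.0969 with an estimated correlation. Leaving out control replicate 1, control replicate 2, Dox replicate 1 and Dox replicate 2 in turn, 14, 14, 29 and 26 p53 targets rose and 1, 1, 1 and 3 fell, 2, 3, 6 and 6 secretory genes fell and 0, 0, 1 and 1 interferon-stimulated genes fell. Under log2(TPM + 1), log2(TPM + 0.1) and a 1.5-fold threshold in turn, 26, 28 and 29 secretory genes, 4, 4 and 9 p53 targets and 6, 9 and 13 interferon-stimulated genes rose, and 2, 2 and 2 secretory genes and 0, 0 and 0 p53 targets fell. The medians on the TPM scales were 0.79 and 1.55 for secretory genes, 0.53 and 0.59 for p53 targets and 0.43 and 0.80 for interferon-stimulated genes. For all tested genes they were 0.06 and 0.13.

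LMNB1, the B-type lamin gene (chromosome 5, 126776623 to 126837020), fell from 6.51 ± 0.489 CPM to 1.56 ± 0.403 CPM (SD, n = 2 each, edgeR log2 fold change -2.06, SE 0.20, adjusted p = 0.00106). Of 19 nuclear lamina and envelope genes, 9 fell, 0 rose and 10 did not pass (median -0.26), with the same counts when adjusted over the list alone. TMPO, a lamina-associated protein, fell by 1.58 (SE 0.07) and the chromatin protein HMGB2 fell by 1.42 (SE 0.09), and camera gave the list adjusted p = 2.07e-05, or adjusted p = 0.102 with an estimated correlation. Heterochromatin and DNA methylation genes fell in 8 of 25 cases and 16 did not pass, with the same counts when adjusted over the list alone. EZH2, the Polycomb methyltransferase, fell by 0.98 (SE 0.14) and UHRF1, which recruits the maintenance DNA methyltransferase, fell by 0.69 (SE 0.10), while ATRX (0.75), named after its value was seen, was the 1 that rose. This list did not pass by camera (adjusted p = 0.0674, adjusted p = 0.253 with an estimated correlation), and its median of -0.17 was 0.03 on the log2(TPM + 1) scale. On that scale the median of all tested genes was itself 0.06. The heterochromatin median was -0.07 without Dox replicate 1 and -0.33 without Dox replicate 2, and that of the lamina list was -0.39 without Dox replicate 2. With control replicate 1, control replicate 2, Dox replicate 1 and Dox replicate 2 left out in turn, 3, 2, 9 and 14 heterochromatin genes fell and 1, 1, 5 and 4 rose, and 5, 5, 12 and 16 lamina genes fell and 0, 0, 2 and 2 rose. Under log2(TPM + 1), log2(TPM + 0.1) and a 1.5-fold threshold in turn, 1, 1 and 4 lamina and 0, 0 and 0 heterochromatin genes fell and 0, 0 and 0 heterochromatin genes rose, with lamina medians of -0.09 and -0.14 on the TPM scales.

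Contractile and myofibroblast genes fell in 11 of 19 cases and 6 did not pass (median -0.48), while 2 rose and 13 fell when adjusted over the list alone. ACTA2, smooth muscle actin, fell from 777 ± 10.1 CPM to 156 ± 5.28 CPM (SD, n = 2 each), and the 2 that rose, named after their values were seen, were CCN1 (0.60) and ANKRD1 (1.08). Camera gave the contractile list adjusted p = 1.45e-07, or adjusted p = 0.195 with an estimated correlation. Collagen and fibroblast matrix genes moved both ways, with 14 of 36 falling, 9 rising and 13 not passing (median -0.23), while 10 rose and 17 fell when adjusted over the list alone. COL11A1 fell by 1.49 (SE 0.07) and the matricellular THBS2 fell by 1.58 (SE 0.08), and camera gave the list adjusted p = 0.00313, or adjusted p = 0.447 with an estimated correlation. Of the fibroblast markers, DCN (0.33), LUM (0.43), THY1 (0.33) and S100A4 (0.34) rose, and COL3A1 fell by 0.56, PDGFRA fell by 0.88 and PDGFRB fell by 1.05 on the log2 scale. COL1A1 (-0.36), COL1A2 (-0.37) and FAP (-0.02) did not pass. Among markers of other cell types, the keratinocyte genes DSG3 and KRT15 and the immune genes PTPRC and CD68 rose. DSG3, a desmosomal cadherin, had 0 and 0 control and 39 and 45 Dox counts. KRT15 had 25 and 22 control and 103 and 113 Dox counts, PTPRC, the leukocyte antigen CD45, 9 and 11 and 90 and 83, and the lysosomal glycoprotein CD68 251 and 261 and 1023 and 1186. KRT5, KRT1, SOX10 and CD3E had 0 counts in all 4 libraries. Of the melanocyte and endothelial markers, those with enough counts to be tested, PMEL (0.0034), MITF (0.11), VWF (0.87) and TEK (-0.39), did not pass, and the others were too low to test. The collagen list's median was -0.44 without Dox replicate 2, and 4, 4, 15 and 11 of its genes rose without control replicate 1, control replicate 2, Dox replicate 1 and Dox replicate 2 in turn. Under log2(TPM + 1), log2(TPM + 0.1) and a 1.5-fold threshold in turn, 3, 3 and 5 contractile and 2, 3 and 6 collagen genes fell, and 0, 0 and 1 contractile and 1, 1 and 1 collagen genes rose, with collagen medians of -0.08 and -0.09 on the TPM scales.

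Lysosome genes rose in 17 of 37 measured cases, 2 fell and 18 did not pass (median 0.29), and 18 rose and 3 fell when adjusted over the list alone. GM2A, a ganglioside activator protein, rose by 2.06 (SE 0.08) and the fucosidase FUCA1 by 1.65 (SE 0.09), while GUSB (-0.71) and CTSF (-0.43), named after their values were seen, fell. Camera gave the lysosome list adjusted p = 9.38e-07, or adjusted p = 0.253 with an estimated correlation. Of 24 cholesterol synthesis genes, 6 rose, 0 fell and 18 did not pass (median 0.23), with the same counts when adjusted over the list alone. The transcription factor SREBF2 rose by 0.78 (SE 0.07) and the reductase DHCR7 by 0.98 (SE 0.10), and camera gave the list adjusted p = 0.0132, or adjusted p = 0.195 with an estimated correlation. NRF2 antioxidant targets rose in 5 of 22 cases, 3 fell and 14 did not pass, with the same counts when adjusted over the list alone, and camera did not call the list (adjusted p = 0.789, adjusted p = 0.865 with an estimated correlation). FTH1, the ferritin heavy chain, rose by 1.37 (SE 0.08) and the aldose reductase AKR1B1 by 0.93 (SE 0.08). Named after their values were seen, HMOX1 (0.53), ABCC1 (0.51) and AKR1C1 (0.58) also rose, and NQO1 (-0.67), GCLC (-0.69) and SLC7A11 (-1.27) fell. The unfolded protein response list split, with 7 of 22 rising, 7 falling and 8 not passing, with the same counts when adjusted over the list alone. ASNS, asparagine synthetase, fell by 1.97 (SE 0.07) and the pseudokinase TRIB3 fell by 2.29 (SE 0.14). Its median was 0.06, its mean -0.17 and camera's direction downward, without passing (adjusted p = 0.0573, adjusted p = 0.253 with an estimated correlation), although the list passed without control replicate 1 (camera adjusted p = 0.0207) and without control replicate 2 (0.0248). The lysosome median was 0.16 without Dox replicate 2, and that of the unfolded protein response list 0.09 without Dox replicate 1 and 0.02 without Dox replicate 2. Without control replicate 1, control replicate 2, Dox replicate 1 and Dox replicate 2 in turn, 11, 12, 26 and 22 lysosome genes rose and 1, 1, 3 and 8 fell, and 4, 4, 13 and 15 cholesterol synthesis genes rose and 0, 0, 1 and 1 fell. In the same order, 2, 2, 8 and 9 NRF2 targets rose and 3, 3, 6 and 8 fell, and 3, 5, 11 and 9 unfolded protein response genes rose. With GC-trend offsets 13 cholesterol synthesis genes rose and 5 lysosome genes fell. Under log2(TPM + 1), log2(TPM + 0.1) and a 1.5-fold threshold in turn, 3, 3 and 9 lysosome, 0, 0 and 1 cholesterol synthesis, 1, 1 and 2 NRF2 and 0, 0 and 2 unfolded protein response genes rose, and 0, 0 and 0 lysosome, 0, 0 and 1 NRF2 and 2, 3 and 5 unfolded protein response genes fell. The unfolded protein response median was 0.15 and 0.16 on the TPM scales and 0.12 with library size alone. On the TPM scales the medians were 0.33 and 0.40 for lysosome and 0.26 and 0.32 for cholesterol synthesis genes.

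**Figure D3:**
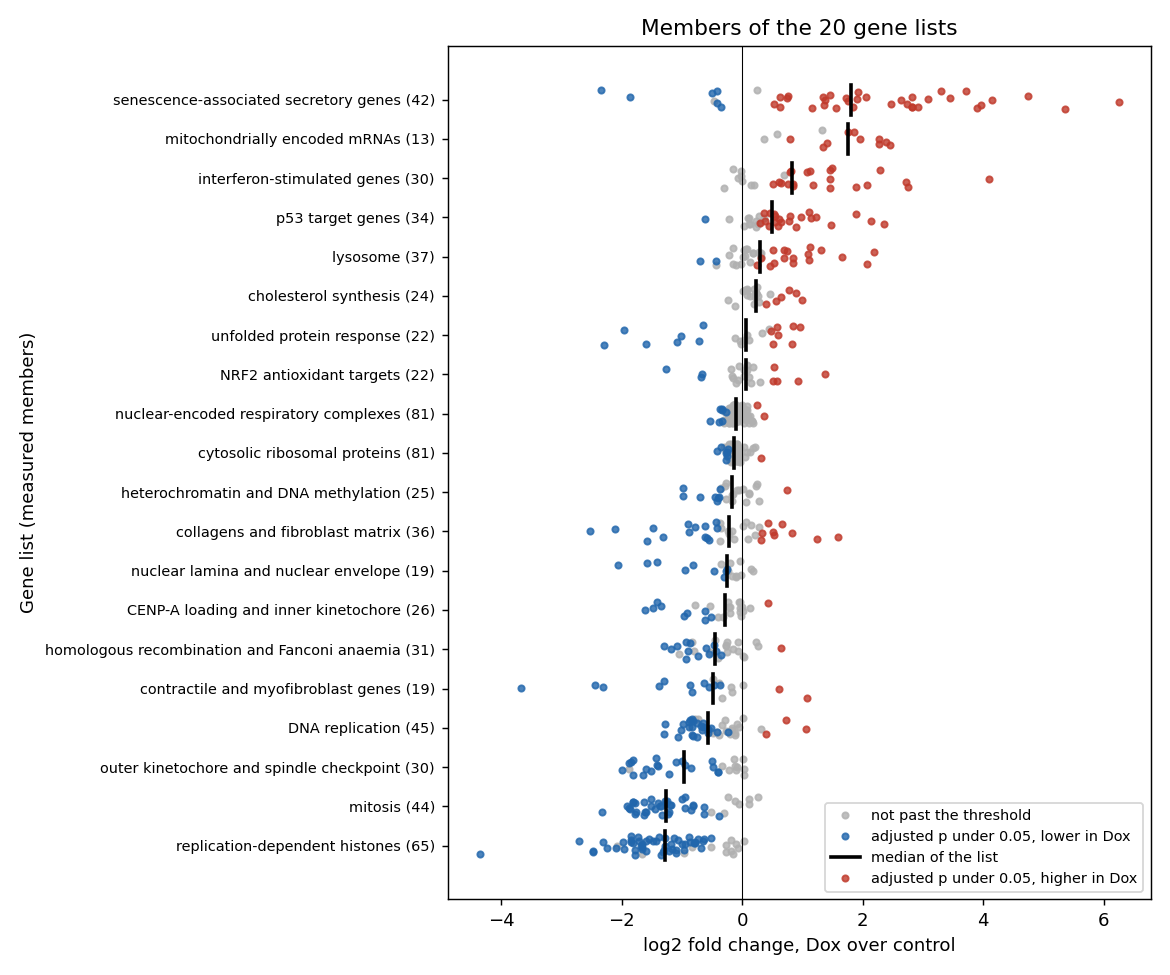
Points are the log2 fold changes (x) of the measured members of 20 gene lists (y, number of members in parentheses), coloured by whether they passed an adjusted p under 0.05, and black bars are list medians. Medians ran from -1.29 for replication-dependent histones to 1.80 for senescence-associated secretory genes.

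Mitochondrially encoded mRNAs rose in 10 of 13 cases, 0 fell and 3 did not pass (median 1.75), and 12 rose and 0 fell when adjusted over the list alone. MT-CO1, a cytochrome oxidase subunit, rose by 1.41 (SE 0.22) and MT-ND5, a complex I subunit, by 2.38 (SE 0.40). MT-ND3 (0.58), MT-ND6 (0.35) and MT-ATP8 (1.32) did not pass over all genes. Camera gave the list adjusted p = 2.88e-05, or adjusted p = 0.388 with an estimated correlation. All mitochondrially encoded genes together held 0.292% (Wilson 95% interval 0.2906 to 0.2938%) and 0.297% (Wilson 95% interval 0.295 to 0.2981%) of counts in the control libraries. The shares were 1.08% (Wilson 95% interval 1.079 to 1.085%) and 0.585% (Wilson 95% interval 0.5824 to 0.587%) in the Dox libraries. The median of the 13 mRNAs was 1.07 without Dox replicate 1 and 2.19 without Dox replicate 2. Nuclear-encoded respiratory complex genes fell in 7 of 81 cases, 2 rose (ATP5IF1, 0.25, and SDHC, 0.36, named after their values were seen) and 72 did not pass, but 0 rose and 0 fell when adjusted over the list alone. NDUFA12 fell by 0.54 (SE 0.09) and NDUFB5 fell by 0.39 (SE 0.08), the list's median was -0.10, or 0.06 on the log2(TPM + 1) scale, and camera did not call it (adjusted p = 0.0616, adjusted p = 0.322 with an estimated correlation). Camera called it without control replicate 1 (adjusted p = 0.0374), Dox replicate 1 (0.0026) or Dox replicate 2 (0.0235). Cytosolic ribosomal protein genes fell in 7 of 81 cases, 1 rose (RPS28, 0.31, named after its value was seen) and 73 did not pass, but 0 rose and 0 fell when adjusted over the list alone. FAU fell by 0.41 (SE 0.09) and RPS23 fell by 0.35 (SE 0.08). The median of all tested genes on the log2(TPM + 1) scale was 0.06. The ribosomal list's median was -0.14, or 0.02 on the log2(TPM + 1) scale, and camera gave adjusted p = 0.0293, or adjusted p = 0.57 with an estimated correlation, and the call was lost without control replicate 2 (adjusted p = 0.0687). FAU, RPS23, NDUFA12 and NDUFB5 did not pass without control replicate 1 (edgeR adjusted p = 0.145, 0.179, 0.0529 and 0.2) or without control replicate 2 (0.148, 0.262, 0.0663 and 0.127). Leaving out control replicate 1, control replicate 2, Dox replicate 1 and Dox replicate 2 in turn, 0, 0, 61 and 50 ribosomal genes fell and 0, 0, 4 and 5 rose, and 0, 0, 35 and 38 respiratory genes fell and 0, 0, 6 and 11 rose. With GC-trend offsets 23 ribosomal and 24 respiratory genes fell. MT-ND5 rose by 1.58 without Dox replicate 1. With library size alone in place of TMM factors, 1 ribosomal gene fell and 2 rose (median -0.07), and 4 respiratory genes fell and 2 rose (median -0.04). On both TPM scales and under a 1.5-fold threshold 0 genes of either list rose or fell, and over all alternatives the falls ranged from 0 to 61 for ribosomal and from 0 to 38 for respiratory genes.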

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

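GC-trend offsets, protein-coding genes alone and sample quality weights were chosen after the data were seen, and the other alternatives before. Against 2757 higher and 2306 lower genes, limma on log2(TPM + 1) called 594 and 198, on log2(TPM + 0.1) 636 and 198, the 1.5-fold threshold (glmTreat) 788 and 483, and GC-trend offsets 3856 and 3797. The TPM + 1 scale moved the median of all genes to 0.06 and the TPM + 0.1 scale to 0.13, and library size alone gave 64.5% higher among its calls in place of 54.5%. Leaving out a library gave 1438 to 4613 higher and 1075 to 5041 lower genes; the lone library of an arm is then assumed to vary like the other pair, and the control pair varied less than the Dox pair. The replicate block gave 2967 and 2515 calls, the shared numbers being no evidence of pairing (correlation of deviations 0.0377 over genes). With an estimated correlation, the adjusted p of the camera calls was 0.0647 for mitosis and secretory genes, 0.0969 for outer kinetochore, replication, p53, interferon and histone genes, 0.102 for lamina, 0.174 for CENP-A loading, 0.253 for lysosome, 0.195 for cholesterol and contractile, 0.212 for recombination, 0.388 for mitochondrially encoded, 0.447 for collagen and 0.57 for ribosomal genes. By fry, adjusted p was 0.0775 for collagen, 0.144 for mitochondrially encoded and 0.057 for ribosomal genes, no longer past 0.05, and 0.0309 for heterochromatin and 0.019 for respiratory genes, now past it. Camera called these also without a low-count filter (heterochromatin 0.000622, respiratory 1.66e-05). The unfolded protein response list passed with the replicate block (0.0359) and GC-trend offsets (0.0218), with 0.0207 to 0.793 on leaving out a library. The ribosomal list did not pass with a filter of 1 CPM in 2 libraries (0.0867) or GC-trend offsets (0.0719), with 6.38e-09 to 0.0687 on leaving out a library, and the respiratory list ranged from 0.0026 to 0.0708. Of the 64 named genes, none changed direction in any of these settings in which it was measured, whereas 23 (TPM + 1) and 19 (TPM + 0.1) of all called genes did; 27 lost the call with TPM + 1, 26 with TPM + 0.1, 13 with the 1.5-fold threshold and at most 6 in any other of these settings. CENPA and OIP5, with 39 and 20 counts over both Dox libraries, did not pass with sample quality weights (adjusted p = 0.0503 and 0.0561 by limma) or the 1.5-fold threshold (0.0613 and 0.0757 by edgeR). Apart from the leave-one-out counts and camera with an estimated correlation, whose construction is given above, the cause of these differences was not tested. A pseudocount by itself shrinks the log2 ratios of low genes, so part of the change on the TPM scales is built in.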

Other observations

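Apart from leaving out single libraries, the lists and tests of this part, GC-trend offsets included, were chosen after the patterns they concern had been seen, and only the summed counts of muscle genes and of nuclear copies and the median with these offsets were still unseen then. Genes of the amino-acid response and tRNA charging fell in 23 of 29 cases, 1 rose (STC2, 0.34) and 5 did not pass (median log2 fold change -0.90, camera adjusted p = 1.25e-23 over 4 added lists, adjusted p = 0.0789 with an estimated correlation). PHGDH, which opens serine synthesis, fell by 1.96, PSAT1, the next enzyme of that route, fell by 1.92 and the amino acid transporter SLC7A5 fell by 1.04 on the log2 scale, and ALDH18A1 (0.04), SLC7A1 (0.03), SLC38A2 (0.10), CEBPB (-0.0031) and VLDLR (-0.17) did not pass. NF-kB targets rose in 12 of 17 measured cases, 1 fell (TRAF1, -0.56) and 4 did not pass (median 0.84, camera adjusted p = 6.25e-13, adjusted p = 0.0633 with an estimated correlation). BIRC3, an inhibitor of apoptosis, rose by 3.04, the mitochondrial superoxide dismutase SOD2 by 2.92 and the NF-kB inhibitor TNFAIP3 by 2.30, and NFKB1 (0.20), BIRC2 (-0.04), VCAM1 (0.85) and IRF1 (-0.11) did not pass. Without control replicate 1, control replicate 2, Dox replicate 1 and Dox replicate 2 in turn, 0, 0, 2 and 2 amino-acid response genes rose and 0, 0, 2 and 2 NF-kB targets fell.

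Complement genes rose in 7 of 13 measured cases and fell in 3 (median 0.35, camera adjusted p = 1.27e-05, adjusted p = 0.0789 with an estimated correlation). CFI, a regulator of the cascade, rose by 1.49 and SERPING1, an inhibitor of its first step, by 1.27, while C1R fell by 0.34, C1S fell by 0.28 and C4B, whose near-identical copy C4A makes its value uncertain, fell by 1.21. The complement genes C4A (-0.66), CFD (-0.75) and CD55 (-0.09) did not pass. Sarcomere genes rose in 4 of 11 measured cases (TTN, NEB, MYPN and NEBL) and fell in 2 (MYH2, -1.01, and MYH3, -0.77), with a median of -0.06 although camera's direction was upward (adjusted p = 0.00234, adjusted p = 0.0953 with an estimated correlation). MYPN rose by 3.01 and NEB, which encodes the thin-filament protein nebulin, by 3.52, while NEBL had 0 and 1 control and 12 and 15 Dox counts, and TCAP (0.43), LDB3 (-0.85), MYOM1 (-0.48) and XIRP1 (-0.69) did not pass. Among long non-coding RNAs, MALAT1 rose by 1.18, NEAT1 by 1.34 and MEG3 by 0.70, and H19 fell by 2.20. With control replicate 1, control replicate 2, Dox replicate 1 and Dox replicate 2 left out in turn, 1, 1, 4 and 4 complement and 1, 1, 4 and 4 sarcomere genes fell, and the sarcomere median was 0.05, -0.17, 0.17 and -0.51.

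CENPA, HJURP and OIP5 fell together, with few counts for CENPA and OIP5. Exact binomial tests of the summed counts gave a largest two-sided p of 3.74e-06, for OIP5, and the mean log2 fold change of the 3 genes was -1.483 (SE 0.159), beside a median of -1.26 for the mitosis list. The 3 were picked because they fell, so neither comparison decides on counting noise or on the share of cycling cells. A smaller share of cycling cells in the Dox libraries and lower levels of these genes within cycling cells cannot be told apart, since no value here separates the 2.

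DSG3, KRT15, PTPRC and TTN, genes typical of other cell types, rose. Cells of those types would bring their abundant transcripts, among which only genes under 10 counts in the controls were summed. For keratinocytes, 8 such genes held 56 counts in the Dox libraries against 300 for DSG3 and KRT15, for blood cells 11 held 33 against 173 for PTPRC, and for striated muscle 11 held 19 against 426 for TTN, but DSC3 (0 to 37 summed counts), KRT16 (15 to 85), KRT17 (728 to 2026), RAC2 (86 to 287) and, outside the lists, CD68 rose. Over all 11, 14 and 14 listed genes, those the controls showed included, the median rise per gene, scaled to library size, was 1.03, 1 and 0 counts (upper quartiles 53.5, 6.77 and 1.75). The rises were 84 for DSG3, 169 for KRT15, 153 for PTPRC and 425 for TTN. These 4 genes were picked because they rose, and counts were not scaled by transcript length. The limit of 10 control counts was not applied to KRT15 and PTPRC, with 47 and 20 summed control counts, while it left out KRT16, KRT17 and RAC2. The sums therefore cannot decide on keratinocytes or blood cells, and the source of DSG3, KRT15, PTPRC, KRT16, KRT17 and RAC2 stays open. Of the 14 muscle genes, 0 passed as higher and 2 as lower. Without scaling by transcript length, this argues only within that limit against muscle cells as the source of TTN. Expression by the fibroblasts themselves under the treatment is a hypothesis that stays open and was not tested.

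Mitochondrially encoded mRNAs rose, with a median log2 fold change of 2.19 without Dox replicate 2 and 1.07 without Dox replicate 1. A single yield factor for all 13 is argued against by Cochran's Q of 69.8 (95% bound 21.0, 12 degrees of freedom), though unequal recovery between transcripts was not tested. That bound takes the 13 as independent with known standard errors. Here their estimated correlation was 0.983 and the standard errors came from 4 libraries, so the bound is only a rough guide. The 388 nuclear copies held 484 control and 1551 Dox counts, the latter equal in size to 0.577% of the rise of the mRNAs. These are reads assigned to the copies, so they cannot show how many reads of the copies were assigned to the mitochondrial genes. This source stays open. With GC-trend offsets the median log2 fold change was 1.76, against 1.75 without them. Over all genes, Dox over control hardly followed GC content (Spearman rho -0.0323), so these offsets could move the median little. The unchanged median is therefore no evidence on GC bias. In bins of genes by GC content, the median log2 ratio of Dox over control ran from -0.0361 to 0.0678. A trend of that size is too small to give the rise, but a GC effect particular to these mRNAs was not tested. An effect of the treatment on mitochondrial RNA may remain, and was not tested.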
